A study of Mus musculus with 12 samples.

How the data were processed

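Whole-liver RNA of MycF/F and MycF/F,ERT2-Cre mice (C57BL/6), fed a control diet or 0.1% Wy-14643 for 2 days, was extracted and amplified to antisense RNA by the authors and read on 12 Agilent mouse arrays of 2 colours, 4 arrays on each of 3 slides. Sample RNA was labelled with Cy5 and a pooled liver reference with Cy3 on all 12 arrays, so a dye effect on a probe is common to all samples and cancels in comparisons between groups. There were 1 MycF/F control array, whose RNA is labelled as pooled, 3 arrays of MycF/F on Wy-14643, 4 of MycF/F,ERT2-Cre on control diet and 4 of MycF/F,ERT2-Cre on Wy-14643. Slide 1 held 1 array of MycF/F on Wy-14643, 2 of MycF/F,ERT2-Cre on control diet and 1 of MycF/F,ERT2-Cre on Wy-14643. Slide 2 held 1 array of each of the 4 groups, and slide 3 held 1 of MycF/F on Wy-14643, 1 of MycF/F,ERT2-Cre on control diet and 2 of MycF/F,ERT2-Cre on Wy-14643. Each slide was scanned at its own time, so slide and scan are the same factor. Tamoxifen treatment, sex and animal identity are not given in the sources used here.

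The deposited spot intensity values, medians of the Cy5 and Cy3 signal and of the local background in scanner units, come from Agilent Feature Extraction 11.0.1.1 per the file headers. The deposited log ratio column is a log10 ratio of Cy5 to Cy3 after the background and dye corrections of that software, per the file headers, and it was used only as an alternative. Each array held 45018 spots, 43379 of them not control spots, for 41174 distinct probes. The plan took gene names from a column that the deposited values lack, so the probes' accessions were matched to symbols through a RefSeq gene table of GRCm38.p6. Of 17440 distinct RefSeq mRNA accessions 16792 were matched, and 23374 probes received 1 symbol. Probes without a symbol stayed in the fits under their accession. The build given in the array design differs from that of the table and no genome sequence was at hand, so no probe was placed on a gene.

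Values were computed in R 4.3.3 with limma 3.58.1, statmod 1.5.0 and data.table version 1.17.8. Median signals were corrected with normexp (offset 50) against the median local background, and the log2 ratio was loess-normalized within each array. Spots that the software marked as outliers were left out, and spots of the same probe were averaged. A probe was kept if its Cy5 signal was well above background on at least 3 of the 12 arrays, which left 31861 probes, 20453 of them with a symbol. For a probe with several spots a share of 0.5 of them had to be well above background. Each gene was represented by its brightest kept probe over all arrays, giving 25260 genes or unnamed probes, 14627 with a symbol, and 4229 had a missing value on at least 1 array. In the fits with a block, contrasts are approximate for genes with missing values. Median Cy5 signal over background ran from 2.69 to 4.76, and 64.6% to 77.1% of spots were well above background. No Cy5 spot was saturated. Outlier spots made up 5.47% to 8.35% of each array on slide 1, 1.31% to 1.84% on slide 2 and 0.904% to 1.58% on slide 3.

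A linear model with 1 mean per group was fitted to all 12 arrays (8 residual degrees of freedom) with lmFit and eBayes, so that the 4 groups share 1 estimate of the spread. The 5 comparisons were Wy-14643 against control diet in each genotype, MycF/F,ERT2-Cre against MycF/F on each diet, and the difference of the drug effects (interaction). Comparisons that use the lone MycF/F control array assume that it varies like the arrays of the other groups, and the same holds for any gene left with 1 array in a group. Tests were two-sided, and p-values were adjusted by Benjamini-Hochberg over all genes tested in a comparison, with calls at an adjusted p under 0.05. The median SE of a log2 fold change was 0.106 and 0.17 for the drug in MycF/F,ERT2-Cre and MycF/F livers, 0.114 and 0.165 for genotype on Wy-14643 and on control diet, and 0.20 for the interaction. The 95% interval reached, by the median, this far to each side: 0.233, 0.371, 0.249, 0.36 and 0.438.

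For gene lists, 35 lists with 609 symbols were tested, of which 557 distinct genes were measured. The lists covered peroxisomal and mitochondrial fatty acid oxidation, other PPARA-responsive lipid genes, G1/S and DNA replication, G2/M and mitosis, ribosome biogenesis, other genes reported as MYC-bound or MYC-responsive, bile acid, cholesterol and fatty acid synthesis, gluconeogenesis, urea cycle, acute phase, complement and coagulation, xenobiotic metabolism, NRF2, p53, ER stress, interferon, immediate early and clock genes. Further lists were male-biased, female-biased, pericentral, periportal and hepatocyte identity genes and markers of cholangiocytes, Kupffer cells, stellate cells, endothelium, lymphocytes, neutrophils, erythroid cells, pancreatic acinar cells and adipocytes. Each list was tested in each comparison with limma camera, which compares a list with all other genes, at a preset inter-gene correlation of 0.01 and again with an estimated one, adjusting over the 35 lists. Missing values were filled with the gene's group mean for this test. Where a gene had no value in a group, its mean over all measured arrays was used instead. Some genes sit in more than 1 list. The urea cycle and periportal lists share 6 or more symbols with others, and 0 of the 17 Kupffer cell symbols are in another list.

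Genes named are Myc, Krt23 and Ppara in every comparison, then the 8 highest and 8 lowest called fold changes in the 2 replicated comparisons and the 5 highest and 5 lowest in the others. These needed a symbol, a brightness at or above the median and no overlap between the arrays of the groups. Of each called list up to 3 members with the smallest adjusted p were named, and of other lists up to 2. Some genes that meet this rule are not reported here. Analyses, lists, naming rule and most alternatives were fixed before the data were examined. Another 2 alternatives, keeping the outlier spots and leaving out the 4 arrays of slide 1, were added after that.

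Alternatives were no background correction, the deposited log ratios, Aquantile between arrays, Cy5 alone scaled to the 75th percentile, no filter, a filter on all 12 arrays, the mean over a gene's probes, fits on the compared groups only, eBayes with trend and robust, array weights, the replicate number as a block, slide as a block, and each array left out in turn. The procedure was tested on simulated data with 200 changed genes per comparison. For changes of 0.5, 1 and 2 (log2) it called 37 of 67, 66 of 67 and 66 of 66 in the drug comparison of MycF/F,ERT2-Cre livers, and 21, 63 and 66 between genotypes on Wy-14643. In MycF/F livers on the drug it called 0, 50 and 65, between genotypes on control diet 5, 41 and 65, and for the interaction 4, 39 and 65. Between 2 and 10 unchanged genes of 25260 were called. A list of 20 genes shifted by 0.5 was called in 20 of 20 simulations in each comparison, and 0 to 2 of 680 unshifted lists were. The simulated genes varied independently of each other and without a slide effect. These rates therefore do not measure the errors of camera for lists of correlated genes.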

Results

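Whole-liver RNA of C57BL/6 mice with MycF/F alleles, with or without an ERT2-Cre transgene, was profiled on 12 Agilent mouse arrays after 2 days on a control diet or on a diet with 0.1% Wy-14643. Wy-14643 is an agonist of PPARα, the nuclear receptor that switches on fatty acid oxidation genes in hepatocytes. Sample RNA was read in Cy5 and a pooled liver reference in Cy3 on every array, so each value is a log2 ratio to that reference. The groups were MycF/F on control diet (n = 1, RNA labelled as pooled liver), MycF/F on Wy-14643 (n = 3), MycF/F,ERT2-Cre on control diet (n = 4) and MycF/F,ERT2-Cre on Wy-14643 (n = 4). The labels give neither tamoxifen treatment nor sex nor animal identity. They do not say that the samples are separate animals, so the p-values measure a spread between samples that may be technical. Median Cy5 signal over background was 4.41 for the MycF/F control array and 3.27, 4.35 and 4.19 for MycF/F on Wy-14643. It was 3.63, 2.69, 3.59 and 4.44 for MycF/F,ERT2-Cre on control diet and 4.25, 4.76, 3.63 and 3.94 for MycF/F,ERT2-Cre on Wy-14643. The number of arrays per group limits the precision.

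Diet was the main axis of the 12 profiles. The first principal component held 46.8% of the variance and parted the diets, and the second (16.7%) set the 4 arrays of slide 1 apart from those of slides 2 and 3. Across genes, which are not independent replicates, arrays of MycF/F and MycF/F,ERT2-Cre livers on Wy-14643 correlated at a mean r of 0.769. Arrays of MycF/F,ERT2-Cre livers on different diets correlated at a mean r of 0.386.

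Myc, the gene carrying the floxed alleles, was read by 3 probes. Cre recombinase removes the stretch between loxP sites, and the ERT2 fusion keeps it out of the nucleus until an estrogen receptor ligand such as tamoxifen is given. The first probe (mean of 10 spots) read 0.22 in the MycF/F control array, 0.90, 0.53 and 0.88 in MycF/F on Wy-14643, -0.85, -0.22, -0.91 and -1.05 in MycF/F,ERT2-Cre on control diet and -1.20, -1.15, -0.96 and -1.03 in MycF/F,ERT2-Cre on Wy-14643. A second probe, with 1 spot, read 0.20 in the MycF/F control array and a mean of 0.65 (SD 0.32, n = 3), -0.85 (SD 0.35, n = 4) and -1.18 (SD 0.20, n = 4) in the same order of groups. The third and brightest probe, which stands for Myc under the gene rule, read 0.58 in the MycF/F control array, 0.62 and 0.51 in 2 arrays of MycF/F on Wy-14643, 0.72, 0.41, 0.42 and 0.01 in MycF/F,ERT2-Cre on control diet and -0.01, 0.05 and -0.07 in 3 arrays of MycF/F,ERT2-Cre on Wy-14643. On Wy-14643 the genotypes differed by -1.85 (SE 0.17, limma adjusted p = 0.0036) on the first probe, by -1.83 (SE 0.19, adjusted p = 0.00775) on the second, and by -0.57 (SE 0.17, adjusted p = 0.281) on the brightest. On control diet the first probe differed by -0.98 (SE 0.25), the second by -1.04 (SE 0.28) and the brightest by -0.19 (SE 0.21), each with adjusted p = 1 and with 1 MycF/F array. The probes were not placed on the gene, and a probe outside the deleted part checks nothing about the deletion.

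**Figure D1:**
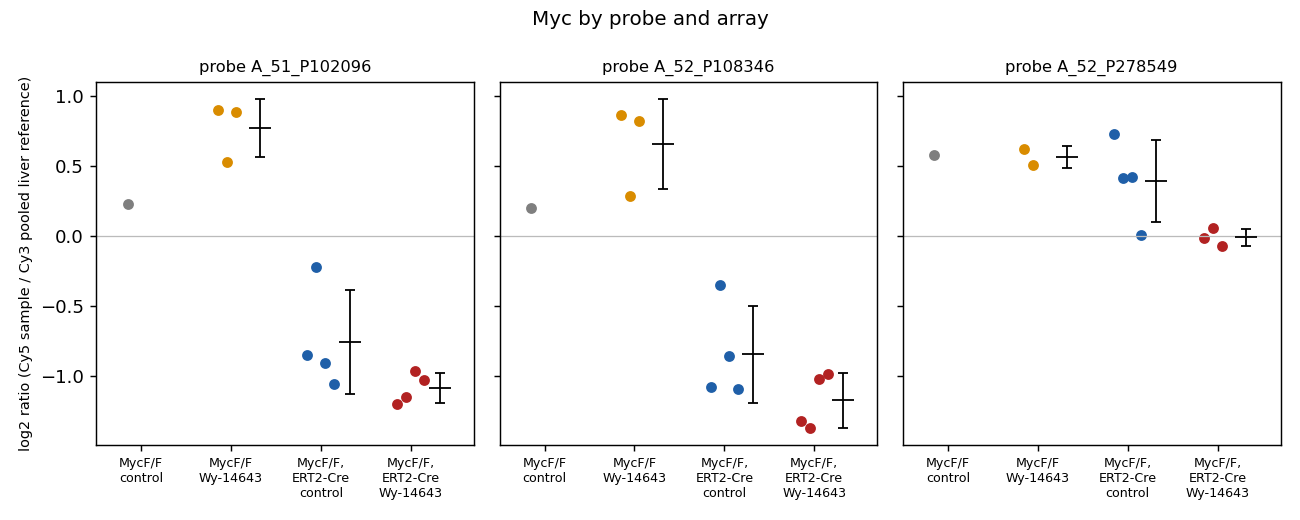
Log2 ratio to the reference for each of the 3 Myc probes (1 panel each) by array and group, with the group mean and SD beside the points. The first probe lies between -1.20 and -0.22 in the 8 MycF/F,ERT2-Cre arrays and between 0.22 and 0.90 in the 4 MycF/F arrays, while the brightest probe spans a narrower range.

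In MycF/F,ERT2-Cre livers, Wy-14643 diet (4 arrays against 4) raised the cytochrome genes Cyp4a14 by 4.65 (SE 0.35, 25.1-fold) and Cyp4a31 by 3.82 (SE 0.25, n = 3 and 4) on the log2 scale. Fatty acid oxidation genes rose too, with Ehhadh up 12.1-fold (SE of log2 0.12, n = 3 and 4) and Pex11a at 2.64 (SE 0.10). Genes of secreted plasma proteins fell, among them Mbl2 by 3.16 (SE 0.17, n = 4 and 2) and Alb by 1.39 (SE 0.13). PPARα with its partner RXR binds response elements near many genes that oxidise or store fatty acids, and the Cyp4a enzymes hydroxylate fatty acids at the omega end.

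Limma called 4114 of 25163 genes at an adjusted p under 0.05, 2242 higher and 1872 lower on Wy-14643, and 695 of them changed at least 2-fold (360 higher, 335 lower). The smallest adjusted p was 3.68e-09. With slide as a block 4646 genes passed (2589 higher, 2057 lower). Within slides 1, 2 and 3 the called genes kept their sign in 99.8%, 99.4% and 100% of cases. The same arrays gave the calls, so this agreement is largely built in. On Cy5 alone 899 genes passed, 42 of the 92 named calls were lost and 1 turned. With the deposited log ratios 5 named calls were lost. The highest changes by the naming rule were Cyp4a12b (5.24, SE 0.17, adjusted p = 1.9e-06, n = 3 and 1), Cyp4a14 (adjusted p = 3.1e-06), Cyp4a10 (4.45, SE 0.18, adjusted p = 2.01e-07, n = 4 and 2), Acot1 (4.17, SE 0.19, adjusted p = 3.95e-07, n = 4 and 3), Cyp4a31, G0s2 (3.72, SE 0.34, n = 3 and 3), Ly6d (3.71, SE 0.19) and Cidec (3.67, SE 0.13, adjusted p = 2.08e-08). The lowest were Cyp2c70 (-3.38, SE 0.18, n = 3 and 4), Nnmt (-3.30, SE 0.31), Slco1a4 (-3.26, SE 0.29), Slc22a7 (-3.26, SE 0.16), Mbl2, Lifr (-3.02, SE 0.24, n = 4 and 2), Thrsp (-2.76, SE 0.37, n = 3 and 1) and Pklr (-2.74, SE 0.21), with adjusted p from 1.82e-07 for Slc22a7 to 0.00133 for Thrsp. Cyp4a12b and Thrsp rest on 1 control array each, so the spread of that arm is borrowed from the other groups. With outlier spots kept they were at 4.86 (SE 0.21) and -3.45 (SE 0.41). For Lifr 3 other probes gave -0.88 to -0.55. The keratin gene Krt23 rose by 3.34 (SE 0.26, 10.2-fold, adjusted p = 4.17e-06), with 2.53, 3.86 and 4.04 within slides 1, 2 and 3. Ppara itself was at 0.10 (SE 0.10, adjusted p = 0.598), and Myc by its brightest probe at -0.40 (SE 0.14, adjusted p = 0.091). Myc passes without MycF/F,ERT2-Cre control replicate 4 (-0.53, adjusted p = 0.0114).

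Fatty acid oxidation rose as lists in MycF/F,ERT2-Cre livers. Of the 17 peroxisomal genes 16 rose and 1 did not pass (16 rose adjusted over the list alone), with a median of 1.75 (camera adjusted p = 1.67e-24; slides 1.53, 1.71 and 2.18) and Acot8 at 1.75 (SE 0.09). Of the 24 genes of mitochondrial fatty acid oxidation and ketogenesis 20 rose (22 adjusted over the list alone; median 1.48, adjusted p = 1.67e-24; slides 1.51, 1.25 and 1.55), such as Slc25a20 (1.78), Hadha (1.75) and Ucp2 (2.17; 2 other probes 0.35 and 3.10). Of the 22 other PPARA-responsive lipid genes 18 rose (19 adjusted over the list alone; median 2.19, adjusted p = 7.39e-21; slides 2.13, 1.61 and 2.37), with Mgll at 2.69 (SE 0.10, n = 3 and 3). All 3 calls hold with an estimated correlation (adjusted p = 0.00837, 0.00213 and 0.00213).

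Genes of secreted plasma proteins and of hepatocyte function fell on Wy-14643. In the list of complement and coagulation genes 17 of 22 fell (18 adjusted over the list alone; median -1.03, adjusted p = 1.53e-18; slides -1.01, -0.95 and -1.06), with F11 at -2.32 (SE 0.10) and C8b at -2.03 (SE 0.09, n = 3 and 3). Of the 21 acute phase genes 11 fell (13 adjusted over the list alone; median -1.15, adjusted p = 2.04e-11; slides -1.12, -0.81 and -1.16), including Itih4 (-1.68), Hpx (-1.67) and Fgg (-1.43). Hepatocyte identity genes, which include the albumin and apolipoprotein genes, fell for 9 of 14 (10 adjusted over the list alone; median -0.69, adjusted p = 3.9e-12; slides -0.04, -0.95 and -0.87), with Apoc3 at -2.15 and Ahsg at -1.92. Periportal genes, expressed near the incoming portal blood, fell for 8 of 10 (8 adjusted over the list alone; median -1.34, adjusted p = 7.37e-10; slides -2.47, -1.15 and -1.64), with Hal at -2.43 (n = 4 and 2). In the pericentral list 4 of 13 fell and 1 rose (5 and 2 adjusted over the list alone; median -0.13, adjusted p = 0.000693; slides -0.50, -0.18 and -0.18), with Slc1a2 at -0.87 and Lect2 at -0.98. The pericentral call is lost without MycF/F,ERT2-Cre control replicate 4 (median -0.08, adjusted p = 0.126). Gluconeogenesis and glycogen genes fell for 4 of 9 (4 adjusted over the list alone; median -0.50, adjusted p = 1.51e-05; slides -0.90, -0.30 and -0.85), with Slc37a4 at -1.82, Pygl at -1.61 and Fbp1 at -1.43. These 6 list calls hold with an estimated correlation, complement and hepatocyte identity at 0.00103, acute phase and pericentral at 0.0499, periportal at 0.00622 and gluconeogenesis at 0.00837.

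Urea cycle and amino acid genes fell for 12 of 21 and rose for 1 (13 and 1 adjusted over the list alone; median -0.87, adjusted p = 6.85e-11; slides -0.57, -0.67 and -1.12). Ass1, which makes argininosuccinate, fell by 2.69 (SE 0.17, n = 4 and 3), Gls2 was at -2.17 and Prodh at -2.25, and the list had adjusted p = 0.0905 with an estimated correlation. Cholesterol synthesis and uptake genes rose for 6 of 22 and fell for 1 (9 and 2 adjusted over the list alone; median 0.43, adjusted p = 0.016, and adjusted p = 0.399 with an estimated correlation), with medians of -0.26, 1.00 and 0.63 on slides 1, 2 and 3. Its call is lost without MycF/F,ERT2-Cre control replicate 3 (adjusted p = 0.106) or Wy-14643 replicate 3 (adjusted p = 0.0511). Hsd17b7 rose by 1.62 (n = 3 and 1). Xenobiotic metabolism genes, which clear drugs and toxins, fell for 5 of 17 and rose for 2 (7 and 3 adjusted over the list alone; median -0.50, adjusted p = 0.0113, and adjusted p = 0.292 with an estimated correlation), with slide medians of 0.08, 0.03 and -0.75. Cyp1a2 was at -1.84 (n = 3 and 1) and Aldh1a1 at 0.90 (n = 3 and 2), and the xenobiotic call is lost without MycF/F,ERT2-Cre control replicate 4 (adjusted p = 0.17). Female-biased liver genes fell for 4 of 10 (7 adjusted over the list alone; median -1.04, adjusted p = 5.53e-05; slides -0.82, -1.71 and -0.88), with Cux2 at -1.68. This list had adjusted p = 0.0693 with an estimated correlation.

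The 2 cell cycle lists were lower on Wy-14643 with the preset correlation alone. In the list of G1/S and DNA replication genes, which license and copy DNA, 6 of 29 fell (6 adjusted over the list alone; median -0.42, adjusted p = 4.79e-06, and adjusted p = 0.324 with an estimated correlation), with slide medians of -1.16, -0.02 and -0.16. Mcm10 fell by 1.84 (SE 0.16, adjusted p = 1.01e-05) and Tk1 by 0.79. MycF/F,ERT2-Cre Wy-14643 replicate 1, on slide 1, stood apart with a list mean of -0.81, against -0.39 to -0.20 for the other 3, and without it the median was -0.25 and the list still passed. Without the 4 arrays of slide 1 the call is lost (-0.04, adjusted p = 0.0896). Of the 27 genes of G2/M and mitosis 11 fell (14 adjusted over the list alone; median -0.34, adjusted p = 3.96e-06; slides -0.67, -0.31 and -0.19), with Top2a at -1.22 (another probe -0.37), Cdc20 at -1.02 and Ube2c at -0.80. That list had adjusted p = 0.224 with an estimated correlation.

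Interferon-stimulated genes fell for 12 of 17 (15 adjusted over the list alone; median -0.65, adjusted p = 5.69e-09; slides -0.76, -0.60 and -0.47), with Ifit3 at -1.09 (SE 0.18) and Ddx58 at -0.73 (SE 0.11; 2 other probes -0.55 and -0.19). The interferon list had adjusted p = 0.0663 with an estimated correlation. Genes of ER stress and the ATF4 response fell for 7 of 16 (8 adjusted over the list alone, where 1 rose; median -0.41, adjusted p = 1.51e-05; slides -0.22, -0.49 and -0.33), with Hsp90b1 at -0.65 (SE 0.12, n = 3 and 3; adjusted p = 0.00457, and 0.0525 with slide as a block). The ER stress list had adjusted p = 0.0905 with an estimated correlation. Of the lists of non-parenchymal markers 4 passed as lower with the preset correlation and 0 with an estimated one. Kupffer cell and macrophage markers fell for 9 of 15 (12 adjusted over the list alone; median -0.61, adjusted p = 2.52e-07; slides -0.74, -0.61 and -0.27), with Cd5l at -1.08 (n = 4 and 3), Clec4f at -0.76 (n = 4 and 2) and C1qc at -0.68. Endothelial markers fell for 4 of 16 (5 adjusted over the list alone; median -0.29, adjusted p = 2.13e-05; slides -0.34, -0.28 and -0.37), among them Eng (-0.54). With an estimated correlation the adjusted p was 0.0905 for the Kupffer list and 0.0921 for the endothelial list. Stellate cell and fibroblast markers fell for 5 of 15 (7 adjusted over the list alone, where 2 rose; median -0.31, adjusted p = 0.0167, and adjusted p = 0.0712 with an estimated correlation; slides -0.39, -0.10 and -0.27), with Col3a1 at -1.13 (another probe -0.55). Lymphocyte and NK cell markers fell for 3 of 14 (3 adjusted over the list alone; median -0.19, adjusted p = 0.0257, and adjusted p = 0.0885 with an estimated correlation; slides -0.08, -0.20 and -0.25), with Cd79b at -0.57. The lymphocyte call is lost without MycF/F,ERT2-Cre control replicate 3 (adjusted p = 0.0519) or 4 (adjusted p = 0.0509).

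The other 14 lists did not pass camera in MycF/F,ERT2-Cre livers on Wy-14643. Ribosome biogenesis genes had a median of 0.12 (adjusted p = 0.341), with 1 of 27 called (Mrto4, 0.66; 1 adjusted over the list alone). Of the 21 other genes reported as MYC-bound or MYC-responsive 5 rose and 3 fell (6 and 5 adjusted over the list alone; median 0.03, adjusted p = 0.822), with Hspd1 at 0.99 and Odc1 at 1.04. Bile acid genes went both ways, 5 of 19 rising and 7 falling (5 and 8 adjusted over the list alone; median -0.35, adjusted p = 0.0691), with Abcc4 at 1.72 and Slco1a4 at -3.26. Fatty acid and triglyceride synthesis genes did too, 6 of 19 rising and 7 falling (6 and 8 adjusted over the list alone; median -0.40, adjusted p = 0.291), with Me1 at 2.10 (n = 2 and 2) and Pklr at -2.74. NRF2-associated genes had 2 higher and 5 lower of 17 (4 and 6 adjusted over the list alone; median -0.16, adjusted p = 0.115), and Gstm3 fell by 1.44. For p53-associated genes 2 were higher and 3 lower of 16 (2 and 4 adjusted over the list alone; median -0.20, adjusted p = 0.0965), with Fas at 0.97 and Phlda3 at -0.69. Immediate early genes had 3 of 12 lower (5 adjusted over the list alone, where 1 rose; median -0.25, adjusted p = 0.0691), with Ier2 at -1.20, and clock genes had 1 higher and 4 lower of 19 (1 and 5 adjusted over the list alone; median -0.18, adjusted p = 0.0992), with Clock at 0.76 (2 other probes 0.12 and 0.47). The immediate early list passes without MycF/F,ERT2-Cre control replicate 1 (adjusted p = 0.0211). Male-biased liver genes had 3 higher and 3 lower of 8 (3 and 3 adjusted over the list alone), a median of -0.29, a mean of 0.77 and an upward test (adjusted p = 0.824), with Cyp4a12a at 3.57.

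Markers of cholangiocytes (median -0.16, adjusted p = 0.109; 1 higher and 1 lower of 10, and 1 and 1 adjusted over the list alone) and erythroid cells (median -0.25, adjusted p = 0.109; 2 of 5 lower, and 2 adjusted over the list alone) did not pass as lists, though Spp1 was at -0.56 and Alas2 at -1.18. Neutrophil markers (median 0.00, mean -0.07, downward test, adjusted p = 0.822), pancreatic acinar markers (median 0.03, adjusted p = 0.943) and adipocyte markers (median 0.01, mean -0.01, downward test, adjusted p = 0.894) had 0 genes called among 13, 7 and 4 by limma (0 in each adjusted over the list alone). In MycF/F,ERT2-Cre livers 21 of 35 lists thus passed camera, 4 higher and 17 lower. With slide as a block all 21 passed, 9 did so with an estimated correlation, and the median kept its sign within each slide for 19 of the 21. The exceptions were the cholesterol and xenobiotic lists. Signs within slides come from the arrays that gave the calls and are no separate support.

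**Figure D2:**
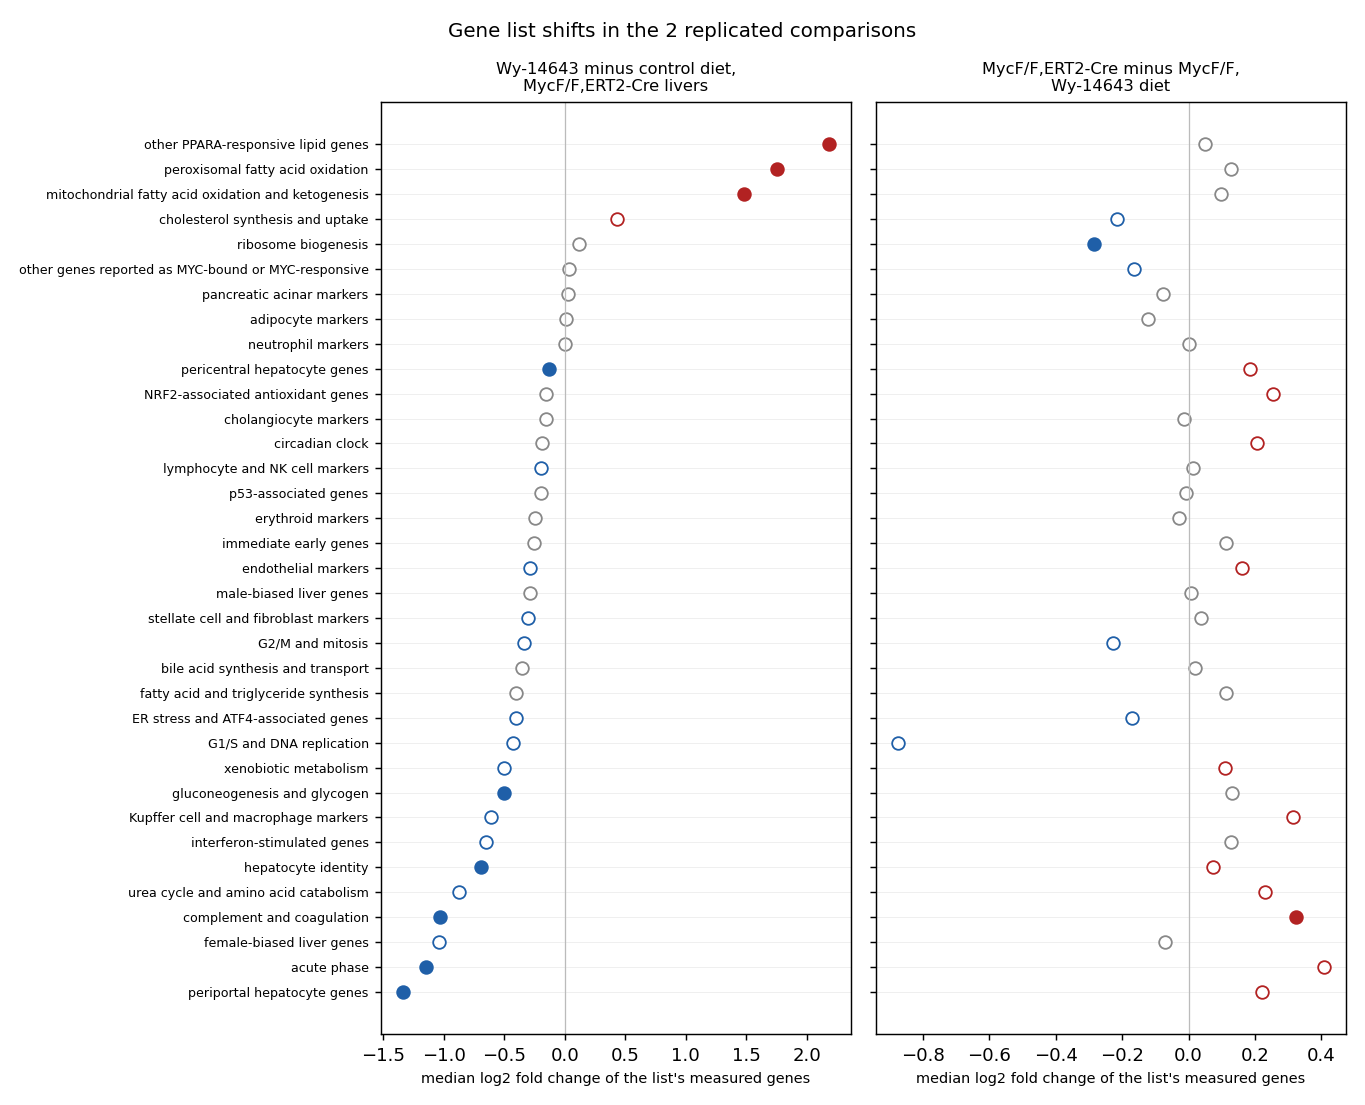
Median log2 fold change of each of the 35 gene lists for Wy-14643 against control diet in MycF/F,ERT2-Cre livers (left) and for MycF/F,ERT2-Cre against MycF/F livers on Wy-14643 (right), red where camera called the list higher, blue where lower, open grey where not called, and filled where the call also holds with an estimated correlation. On the left 21 lists are called and 9 are filled, and on the right 17 are called and 2 are filled.

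Between genotypes on Wy-14643 (4 MycF/F,ERT2-Cre arrays against 3 MycF/F arrays), the spermidine synthase gene Srm was lower in MycF/F,ERT2-Cre livers by a log2 value of -0.64 (SE 0.09, 1.56-fold) and the nucleolar gene Nop56 at -0.65 (SE 0.09, 1.57-fold). The ribosomal protein genes Rplp1 (-0.93, SE 0.08, n = 3 and 3), Rpl12 (-0.80, SE 0.10) and Rps12 (-0.69, SE 0.09) were lower too. Higher in MycF/F,ERT2-Cre livers were the zinc transporter gene Slc39a4 at 1.34 (SE 0.19, 2.53-fold) and the complement genes C8b at 0.97 (SE 0.10, n = 3 and 2) and Cfi at 0.58 (SE 0.08). MYC raises ribosome production and nucleotide and polyamine synthesis in growing cells, and Srm, Nop56 and Ctps are among its textbook targets.

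Limma called 17 of 25171 genes between genotypes on Wy-14643, 4 higher and 13 lower in MycF/F,ERT2-Cre livers, and 2131 had an unadjusted p under 0.05. All 17 had the same sign on every slide that measured them, which is largely built in, since the same arrays gave the calls. Other lower genes were Ctps (-0.98, SE 0.15, adjusted p = 0.0374), Tubb6 (-0.71, SE 0.10, adjusted p = 0.0302), Ppp1r14b (-0.69, SE 0.09) and Pabpc4 (-0.68, SE 0.10). Rplp1 had adjusted p = 0.0155, while Srm, Nop56, Rpl12, Rps12, Slc39a4, C8b and Cfi had adjusted p = 0.0257, as did Ppp1r14b and Pabpc4. With slide as a block 33 genes passed (7 higher, 26 lower), and C8b did not (adjusted p = 0.11). None of the 17 passed on the deposited log ratios or on Cy5 alone. Limma called 0 genes when any MycF/F Wy-14643 replicate was left out, and 0 without MycF/F,ERT2-Cre Wy-14643 replicate 2, 3 or 4. Without MycF/F,ERT2-Cre Wy-14643 replicate 1 it called 9, and without control replicate 1 it called 27. Krt23 was at -0.04 (95% interval -0.66 to 0.58, adjusted p = 0.994) and Ppara at 0.15 (SE 0.11, adjusted p = 0.854).

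Gene lists tied to MYC and to cell division were lower in MycF/F,ERT2-Cre livers on Wy-14643. Ribosome biogenesis genes had a median of -0.28 (camera adjusted p = 1.81e-18, and 0.00164 with an estimated correlation), with 1 of 27 called and 13 lower adjusted over the list alone. The slide medians were -0.26, -0.33 and -0.27, and with slide as a block the adjusted p was 3.08e-15. For the list of G1/S and DNA replication genes the median was -0.87 (adjusted p = 6.81e-23, and adjusted p = 0.132 with an estimated correlation), with 0 of 29 called by limma and 24 lower adjusted over the list alone. Its slide medians were -1.53, -0.54 and -0.43, all 29 members were negative, and the block gave adjusted p = 5.42e-19. Genes of G2/M and mitosis had a median of -0.23 (adjusted p = 3.17e-08, and adjusted p = 0.181 with an estimated correlation; slides -0.45, -0.15 and -0.18; 0 of 27 called and 0 adjusted over the list alone). The other genes reported as MYC-bound or MYC-responsive had a median of -0.16 (adjusted p = 8.82e-06, and adjusted p = 0.0671 with an estimated correlation; slides -0.21, -0.19 and -0.16), with 1 of 21 called (Srm) and 3 lower adjusted over the list alone. Cholesterol genes (median -0.22, adjusted p = 1.97e-05; slides -0.44, -0.11 and -0.22) and ER stress genes (median -0.17, adjusted p = 8.36e-06; slides -0.26, -0.12 and -0.30) were lower as lists, with 0 genes called in either and 0 adjusted over the list alone. With an estimated correlation they had adjusted p = 0.21 and 0.132.

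Complement and coagulation genes were higher in MycF/F,ERT2-Cre livers on Wy-14643. All 22 complement and coagulation genes were positive, with a median of 0.32 (adjusted p = 9.24e-20, and 0.00112 with an estimated correlation), 1 called and 12 higher adjusted over the list alone. The slide medians were 0.42, 0.35 and 0.30, and the block gave adjusted p = 2.8e-17. The albumin gene Alb, in the hepatocyte identity list, was at -0.59 (SE 0.14, adjusted p = 0.163). Acute phase genes had a median of 0.41 (adjusted p = 1.7e-07, and adjusted p = 0.132 with an estimated correlation; slides 0.62, 0.37 and 0.35; 0 of 21 called, 2 higher adjusted over the list alone). Kupffer cell and macrophage markers had a median of 0.31 (adjusted p = 8.36e-06, and adjusted p = 0.181 with an estimated correlation; slides 0.30, 0.34 and 0.38; 0 of 15 called, 5 higher adjusted over the list alone). Urea cycle (0.23, adjusted p = 8.59e-06; slides 0.40, 0.12 and 0.29), periportal (0.22, adjusted p = 6.32e-05; slides 0.30, 0.24 and 0.32) and pericentral genes (0.19, adjusted p = 0.000114; slides 0.02, 0.22 and 0.36) were higher by list median, with 0, 1 and 1 genes passing adjusted over the list alone. These had adjusted p = 0.243, 0.0627 and 0.0521 with an estimated correlation. Endothelial markers (0.16, adjusted p = 0.000114; slides 0.28, 0.32 and 0.02), clock genes (0.21, adjusted p = 0.00144; slides 0.37, 0.17 and 0.19) and NRF2-associated genes (0.25, adjusted p = 0.0018; slides 0.03, 0.19 and 0.42) passed as well. With an estimated correlation they had adjusted p = 0.181, 0.0521 and 0.181, and the genes passing adjusted over the list alone were 1, 0 and 3 (2 higher, 1 lower).

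Xenobiotic (median 0.11, adjusted p = 0.0469) and hepatocyte identity genes (median 0.07, adjusted p = 0.0442) passed narrowly between genotypes, with 0 and 2 members (1 higher, 1 lower) adjusted over the list alone. Slide medians were 0.21, 0.01 and 0.22 for xenobiotic and 0.16, 0.17 and -0.00 for hepatocyte identity genes, the 1 called list of 17 whose sign differed between slides. They had adjusted p = 0.465 and 0.136 with an estimated correlation. The xenobiotic call is lost without MycF/F Wy-14643 replicate 3 (adjusted p = 0.32), MycF/F,ERT2-Cre control replicate 1 (0.0535) or 3 (0.0738), or MycF/F,ERT2-Cre Wy-14643 replicate 1 (0.116) or 3 (0.549). The hepatocyte identity call is lost without MycF/F Wy-14643 replicate 2 (0.131), MycF/F,ERT2-Cre control replicate 1 (0.0535), 2 (0.054) or 3 (0.0542), or MycF/F,ERT2-Cre Wy-14643 replicate 1 (0.137) or 2 (0.13), and with slide as a block (0.0994). Of the 35 lists 17 passed, 11 higher and 6 lower, 16 of them with slide as a block and 2 with an estimated correlation (ribosome biogenesis and complement).

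The PPARA-responsive lists did not pass between genotypes on Wy-14643. Peroxisomal genes had a median of 0.13 (adjusted p = 0.059, and 0.00902 with slide as a block, 0.0415, 0.0291 and 0.0352 without MycF/F,ERT2-Cre control replicate 2, 3 and 4). Mitochondrial fatty acid oxidation genes had 0.10 (adjusted p = 0.166, and 0.0365 without MycF/F Wy-14643 replicate 1). The other PPARA-responsive genes had a median of 0.05, a mean of 0.03 and a downward test (adjusted p = 0.711), with Cidea at -0.74 (SE 0.15, adjusted p = 0.105) and Cd36 at -0.61 (SE 0.15, adjusted p = 0.164). Gluconeogenesis genes had 0.13 (adjusted p = 0.207, and 0.00756 without the MycF/F control array) and fatty acid synthesis genes 0.11 (adjusted p = 0.19). Bile acid (0.02, adjusted p = 0.371), p53 (-0.01, adjusted p = 0.411), interferon (0.13, adjusted p = 0.198), immediate early (0.11, adjusted p = 0.303), male-biased (0.01, mean -0.02, upward test, adjusted p = 0.634) and female-biased genes (-0.07, adjusted p = 0.824) did not pass. Nor did markers of cholangiocytes (-0.01, adjusted p = 0.31), stellate cells (0.04, adjusted p = 0.181), lymphocytes (0.01, mean -0.01, downward test, adjusted p = 0.77), neutrophils (0.00, adjusted p = 0.943), erythroid cells (-0.03, adjusted p = 0.634), acinar cells (-0.08, adjusted p = 0.461) or adipocytes (-0.12, adjusted p = 0.0808, and 0.0374 without MycF/F Wy-14643 replicate 2).

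**Figure D3:**
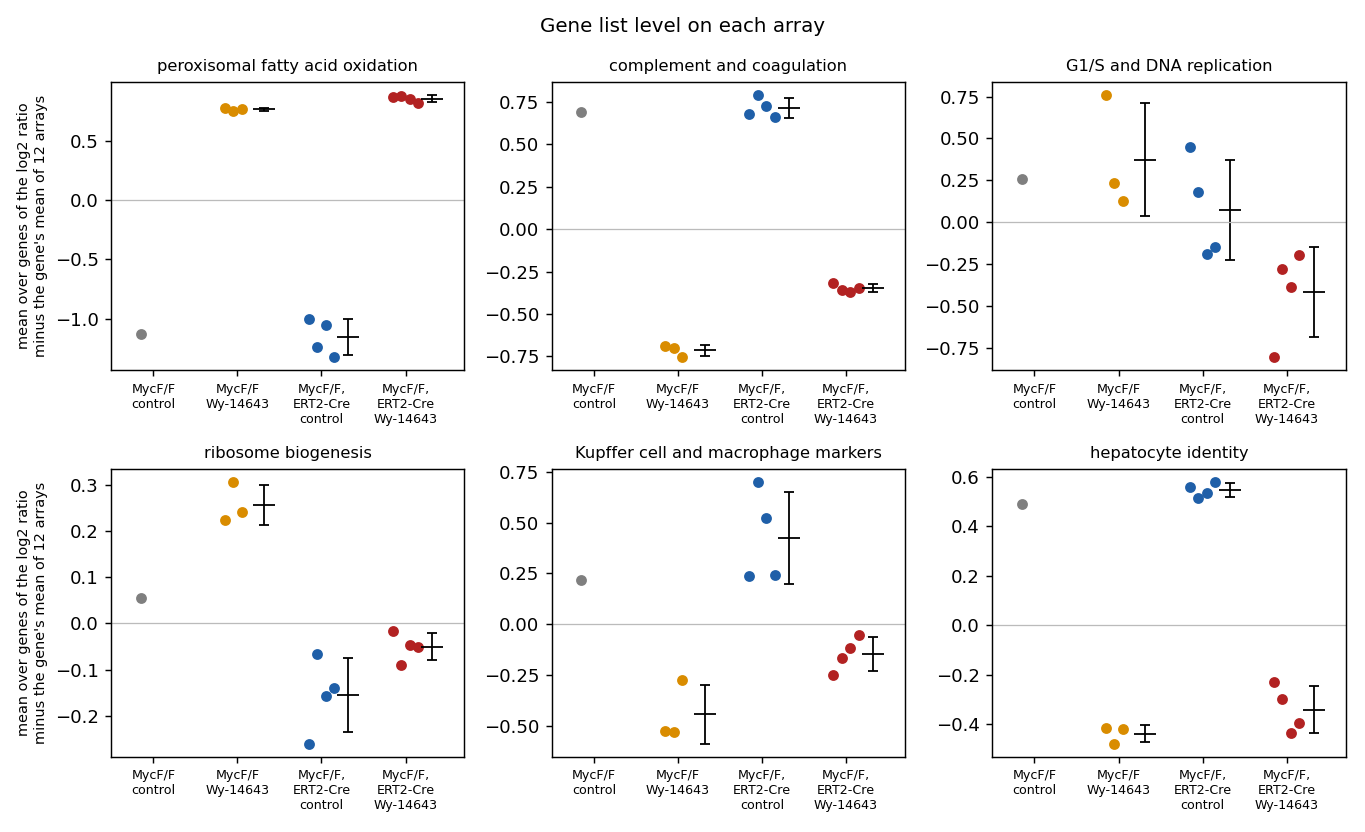
Mean log2 ratio to the reference of 6 gene lists in each of the 12 arrays by group, each member centred over the arrays, with the group mean and SD beside the points. Complement and coagulation genes lie at -0.75 to -0.69 in MycF/F and at -0.37 to -0.32 in MycF/F,ERT2-Cre arrays on Wy-14643, against 0.66 to 0.79 in the 5 control diet arrays.

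In MycF/F livers (3 Wy-14643 arrays against 1 control array of pooled RNA), Wy-14643 raised Acot1 by 4.45 (SE 0.30, 21.9-fold, n = 2 and 1), Cyp4a10 by 4.13 (SE 0.24, 17.5-fold) and Cidec by 4.05 (SE 0.21). Thrsp, a lipogenesis gene, was at -3.87 (SE 0.37), Cyp2c70 at -3.49 (SE 0.27) and Nnmt at -3.57 (SE 0.51). The lone control array is assumed to vary like the arrays of the other groups. Mouse liver answers PPARα agonists with more fat oxidation and, over days, with growth.

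Limma called 1635 of 24916 genes in MycF/F livers, 832 higher and 803 lower, with 754 changed at least 2-fold (339 higher, 415 lower). Without MycF/F Wy-14643 replicate 3 it called 544 higher and 553 lower. With slide as a block 1592 passed (778 higher, 814 lower), and all 1635 had the same sign on slide 2, the only slide with both groups. That slide holds the lone control array behind the calls, so the shared sign is no separate support. On Cy5 alone 132 genes passed, 92 higher and 40 lower, while the median over all genes was -0.11 there and -0.00 on the ratios. Further named genes were Cyp4a12b (4.36, SE 0.18, n = 2 and 1), Cyp4a14 (4.15, SE 0.58), Lifr (-3.45, SE 0.34, n = 2 and 1) and Pklr (-3.21, SE 0.34), with adjusted p between 2.16e-06 for Cidec and 0.00106 for Nnmt among the 10 named. For Lifr 3 other probes gave -0.95 to -0.68. Krt23 rose by 3.33 (SE 0.43, adjusted p = 0.000584). Myc by its brightest probe was at -0.02 (SE 0.23, adjusted p = 0.993; the other 2 probes 0.54 and 0.46) and Ppara at -0.06 (SE 0.17, adjusted p = 0.945).

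The same lists led in MycF/F livers. Peroxisomal (median 1.95, 14 of 17 higher, 15 adjusted over the list alone), mitochondrial fatty acid oxidation (1.32, 17 of 24, 20 adjusted over the list alone) and other PPARA-responsive genes (2.58, 14 of 22, 18 adjusted over the list alone) rose, with camera adjusted p = 1.8e-28, 8.92e-29 and 1.85e-25. On slide 2 their medians were 1.86, 1.41 and 2.69. Complement (-1.43, 18 of 22 lower, 19 adjusted over the list alone), acute phase (-1.47, 7 of 21, 15 adjusted over the list alone), periportal (-1.75, 6 of 10, 8 adjusted over the list alone) and hepatocyte identity genes (-0.81, 7 of 14, 9 adjusted over the list alone) fell, with adjusted p = 9.62e-29, 1.14e-14, 4.65e-12 and 1.74e-11 and slide 2 medians of -1.32, -1.56, -1.91 and -0.75. These 7 calls hold with an estimated correlation, the highest at 0.0324 for acute phase genes. C8b fell by 2.59 (SE 0.14, n = 2 and 1), Itih4 by 2.59 (SE 0.37), Ehhadh was at 3.61 (SE 0.19) and Hal at -2.80 (SE 0.27).

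Another 12 lists passed in MycF/F livers with the preset correlation alone. Higher were cholesterol genes (median 0.54, 2 of 22, and 2 adjusted over the list alone, adjusted p = 1.98e-05; adjusted p = 0.186 with an estimated correlation) and ribosome biogenesis genes (0.18, adjusted p = 0.00316; adjusted p = 0.128 with an estimated correlation), with Mrto4 at 0.91, 1 of 27 called and 1 adjusted over the list alone. Lower were urea cycle (-0.71, adjusted p = 2.19e-11), Kupffer cell (-0.69, adjusted p = 9.77e-07), interferon (-0.60, adjusted p = 1.16e-05) and endothelial genes (-0.30, adjusted p = 0.00019). Of their 21, 15, 17 and 16 members 9, 3, 2 and 1 fell, and 10, 10, 5 and 2 adjusted over the list alone. With an estimated correlation these had adjusted p = 0.128, 0.135, 0.136 and 0.14. Female-biased (-0.79, adjusted p = 0.00169), clock (-0.40, adjusted p = 0.0113), bile acid (-0.69, adjusted p = 0.0287) and gluconeogenesis genes (-0.23, adjusted p = 0.0375) were lower too. They had adjusted p = 0.135, 0.0706, 0.186 and 0.128 with an estimated correlation. Of their members 4 of 10, 1 of 19, 8 of 19 and 4 of 9 fell, and 4, 1, 10 and 4 adjusted over the list alone. The pericentral (-0.03, adjusted p = 0.0375) and G2/M lists (-0.17, adjusted p = 0.0463) had adjusted p = 0.14 and 0.532 with an estimated correlation, with 3 and 0 genes lower and 4 and 0 adjusted over the list alone.

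Single arrays decided 3 of these list calls in MycF/F livers. The G2/M call is lost without MycF/F Wy-14643 replicate 2 (adjusted p = 0.159) or 3 (0.0991), MycF/F,ERT2-Cre control replicate 3 (0.0527) or 4 (0.0616), or MycF/F,ERT2-Cre Wy-14643 replicate 2 (0.0502) or 3 (0.058). The pericentral call is lost without MycF/F Wy-14643 replicate 2 (0.146), MycF/F,ERT2-Cre control replicate 1 (0.0515), 3 (0.0522) or 4 (0.0895), or MycF/F,ERT2-Cre Wy-14643 replicate 2 (0.0536) or 3 (0.0582). The gluconeogenesis call is lost without MycF/F Wy-14643 replicate 3 (0.0505), and ER stress genes (-0.30, adjusted p = 0.0697) pass without it (0.00141). G1/S and DNA replication genes had a median of 0.14 (adjusted p = 0.666), though Mcm10 fell by 1.95 (SE 0.26, adjusted p = 0.000792). Male-biased genes (median -0.38, mean 0.53, upward test, adjusted p = 0.674) and acinar markers (median -0.00, mean -0.03, upward test, adjusted p = 0.942) had list values and tests of different sign. All 19 called lists also passed with slide as a block. On slide 2 each had a median of the same sign, though against the same lone control array.

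The drug effects in MycF/F,ERT2-Cre and in MycF/F livers, which share no array, correlated across 24877 genes at r = 0.857 (rho = 0.661), and genes are not independent replicates. Of the 4048 and 1629 genes called among these, 1513 were shared, 766 higher in both and 747 lower in both, with 0 in opposite directions. Independent calls would give 73.6 and 59.1. Both sets of calls use the same estimate of each gene's spread, which can raise the overlap above these values without a shared effect. Of the 4048 genes called in MycF/F,ERT2-Cre livers 3965 had the same sign in MycF/F livers, and of those changed at least 2-fold 663 of 664.

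**Figure D4:**
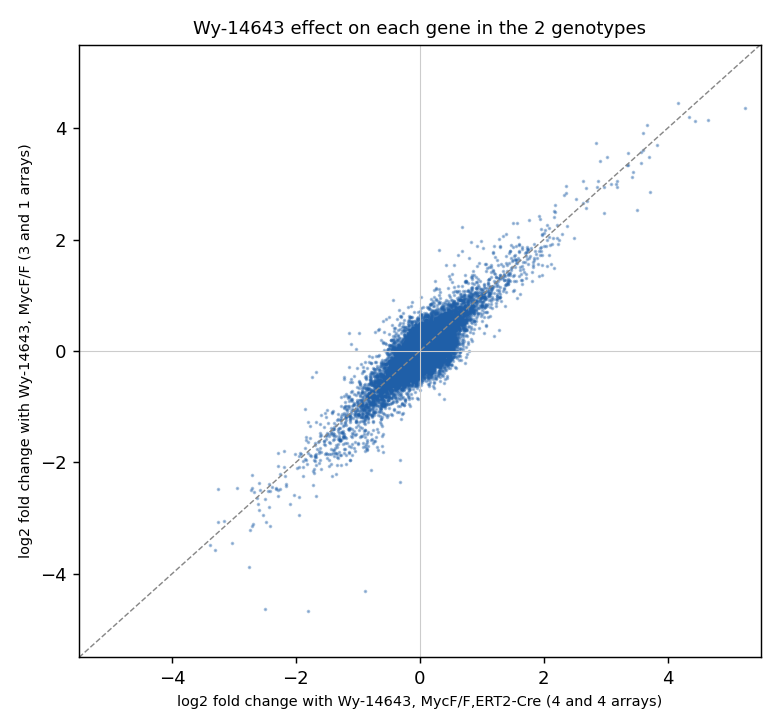
Log2 fold change of each gene for Wy-14643 against control diet in MycF/F,ERT2-Cre livers (horizontal) and in MycF/F livers (vertical), with a dashed line where both are equal. The 24877 genes spread along the line, r = 0.857.

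On control diet (4 MycF/F,ERT2-Cre arrays against 1 MycF/F array of pooled RNA), the male-biased steroid gene Hsd3b5 was at -1.64 (SE 0.23, adjusted p = 0.258), Sult3a1 at -1.41 (SE 0.31, adjusted p = 1) and the periportal gene Cyp2f2 at 0.83 (SE 0.26, adjusted p = 1) in MycF/F,ERT2-Cre livers. Limma called 0 of 24901 genes, with 441 at an unadjusted p under 0.05 and 0 with slide as a block. The genes with an unadjusted p under 0.05 are a smaller share of those tested than the 0.05 expected by chance. With the spread of the MycF/F control arm borrowed from the other groups, this shortfall is no sign that the genotypes are alike. Krt23 was at -0.06 (SE 0.42) and Ppara at -0.01 (SE 0.16), each with adjusted p = 1. Pericentral genes sit around the draining central vein, where Wnt signals keep them on. Their list was higher in MycF/F,ERT2-Cre livers (median 0.23, camera adjusted p = 2.78e-10, and 0.00883 with an estimated correlation; slide 2 0.23), a call lost without MycF/F,ERT2-Cre control replicate 4 (adjusted p = 0.053). All 27 ribosome biogenesis genes were negative (median -0.17, adjusted p = 3.21e-06, and 0.0378 with an estimated correlation; slide 2 -0.22). Gluconeogenesis genes were higher (0.15, adjusted p = 0.000332, and 0.0378 with an estimated correlation; slide 2 -0.04), with 1 of 9 passing adjusted over the list alone.

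The remaining 9 list calls on control diet rest on the preset correlation, with 0 genes passing adjusted over the list alone in each. Higher were endothelial (median 0.16, adjusted p = 0.000556), xenobiotic (0.15, adjusted p = 0.000676), Kupffer cell (0.15, adjusted p = 0.000676), NRF2-associated (0.09, adjusted p = 0.00155) and urea cycle genes (0.08, adjusted p = 0.00234). These had adjusted p = 0.322, 0.405, 0.41, 0.322 and 0.538 with an estimated correlation. Complement (0.18, adjusted p = 0.00592), stellate (0.16, adjusted p = 0.016) and interferon genes (0.19, adjusted p = 0.0175) were higher and the other MYC-responsive genes lower (-0.09, adjusted p = 0.0435). They had adjusted p = 0.159, 0.143, 0.538 and 0.419 with an estimated correlation. With slide as a block 10 of the 12 calls passed, and the urea cycle (0.0688) and interferon lists (0.198) did not. On slide 2 the gluconeogenesis, urea cycle (-0.24) and xenobiotic medians (-0.03) had the other sign.

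Single arrays decided several of the list calls on control diet. Without MycF/F,ERT2-Cre control replicate 4 the urea cycle median was -0.04 (adjusted p = 0.363), the xenobiotic (0.891), stellate (0.053), pericentral (0.053) and other MYC-responsive calls (0.155) were lost and peroxisomal genes passed as higher (0.14, adjusted p = 8.7e-06). Without control replicate 3 the complement (0.14) and other MYC-responsive calls (0.571) were lost. The interferon call is lost without control replicate 1 (0.0879) or 2 (0.297), and the other MYC-responsive call without MycF/F,ERT2-Cre Wy-14643 replicate 1 (0.0573) or 2 (0.0534). G1/S and DNA replication genes had a median of -0.16 (adjusted p = 0.0806) and passed without control replicate 1 (-0.32, adjusted p = 0.000442) or 2 (0.0289) or Wy-14643 replicate 1 (0.0209). G2/M (-0.09, adjusted p = 0.142) and cholesterol genes (0.03, mean -0.02, downward test, adjusted p = 0.361) passed as lower without control replicate 1 (0.000433 and 0.000104). For acute phase genes (median -0.11, mean -0.28, upward test, adjusted p = 0.0806) and ER stress genes (median -0.04, mean -0.08, upward test, adjusted p = 0.215) the list value and the test differed in sign. The upward test of acute phase genes passed without control replicate 1 (0.0112) or Wy-14643 replicate 3 (0.0486), and that of immediate early genes without control replicate 1 (0.00608). The downward test passed for male-biased genes without control replicate 2 (0.0265) and for other PPARA-responsive genes without control replicate 3 (0.0362).

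In the test of whether the drug effect differs between genotypes (interaction), Hsd3b5 differed by 1.63 (SE 0.28) and Krt23 by 0.01 (95% interval -1.09 to 1.11). Myc by its brightest probe differed by -0.38 (SE 0.27) and Ppara by 0.16 (SE 0.20), all with adjusted p = 1. The first and second Myc probes differed by -0.87 (SE 0.30) and -0.79 (SE 0.34), also with adjusted p = 1. Limma called 0 of 24877 genes, with 540 at an unadjusted p under 0.05, a smaller share than the 0.05 expected by chance. The test rests on the lone MycF/F control array with a borrowed spread, so the small share is no sign that the drug effects are alike. As lists, complement and coagulation genes, made by hepatocytes for the plasma, had a difference of 0.16 (camera adjusted p = 1.55e-07, and 0.0325 with an estimated correlation; slide 2 0.09), while the spread of the list in the MycF/F control arm is not measured. The other 6 calls did not hold with an estimated correlation, and 0 genes of the 7 lists passed adjusted over the list alone. G1/S and DNA replication genes differed by -0.63 (adjusted p = 2.76e-10, and adjusted p = 0.416 with an estimated correlation; slide 2 -0.06). Ribosome biogenesis (-0.11, adjusted p = 0.000441), ER stress (-0.14, adjusted p = 6.11e-05), G2/M (-0.15, adjusted p = 0.0094), pericentral (-0.08, adjusted p = 0.0428) and periportal genes (0.32, adjusted p = 0.0117) also passed. They had adjusted p = 0.214, 0.255, 0.641, 0.255 and 0.255 with an estimated correlation, and slide 2 medians of -0.26, -0.17, 0.04, 0.04 and 0.40. G2/M did not pass with slide as a block (0.118).

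Lists called in MycF/F,ERT2-Cre livers and not in MycF/F livers on the drug, or the reverse, did not differ by this test for xenobiotic (adjusted p = 0.297), stellate (0.523), lymphocyte (0.49), bile acid (0.149) and clock genes (0.135). Among these, xenobiotic genes passed without MycF/F,ERT2-Cre Wy-14643 replicate 3 (0.0322). Acute phase genes (0.53, adjusted p = 0.0776) passed without MycF/F,ERT2-Cre control replicate 2 (0.000386) or 4 (0.000669) or Wy-14643 replicate 2 (0.0491) or 3 (0.0046), and with slide as a block (0.00353). Not called with all arrays, the other MYC-responsive (0.0465 without MycF/F Wy-14643 replicate 1, 0.00876 without MycF/F,ERT2-Cre control replicate 3), p53 (0.0342 without MycF/F Wy-14643 replicate 3), cholesterol (0.0456 and 0.029 without control replicate 2 and 3), gluconeogenesis (0.0332 without control replicate 3) and urea cycle lists (2.26e-05 without control replicate 4) passed without single arrays. The peroxisomal list passed upward without control replicate 3 (0.0315) and downward without control replicate 4 (0.00553). Leaving out single arrays changed 4 of the 7 interaction calls. G2/M is lost without MycF/F Wy-14643 replicate 1 (adjusted p = 0.101), MycF/F,ERT2-Cre control replicate 1 (0.129) or Wy-14643 replicate 1 (0.0846). ER stress is lost without MycF/F,ERT2-Cre control replicate 3 (0.083), and periportal genes without it (0.105) or without MycF/F Wy-14643 replicate 3 (0.0867). The pericentral list turned without MycF/F,ERT2-Cre control replicate 4 (0.0036, adjusted p = 0.521), and its call is lost without MycF/F Wy-14643 replicate 1 (0.057), control replicate 1 (0.059) or MycF/F,ERT2-Cre Wy-14643 replicate 1 (0.154) or 4 (0.0979).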

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

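Chosen after the result was seen were the tests on the 4 arrays of slide 1, on the Kupffer cell list, on the interaction of the DNA replication list and on the brightest Myc probe under the drug and the splits within slides, while the counts of other splits, the Myc probe with all spots kept and the saturation count had their predictions written before their values were seen. The setting that keeps all spots was itself added after the data were seen. A single array lay far from the other 3 of its group in 2 of 79 tests of the lists, the Myc probes, Krt23 and Ppara in the 2 groups of 4 arrays, where chance picks about 1 in 20. For bile acid genes MycF/F,ERT2-Cre Wy-14643 replicate 3 was 0.14 above the mean of the other 3, and for interferon-stimulated genes MycF/F,ERT2-Cre Wy-14643 replicate 4 was 0.25 above. With the drug effects of the 2 genotypes set against each other, 7 lists differed by the interaction test with the preset correlation, and 1 of them (complement and coagulation) with an estimated one. The differences were -0.63 for G1/S and DNA replication, -0.15 for G2/M, -0.11 for ribosome biogenesis, 0.16 for complement and coagulation, -0.14 for ER stress, -0.083 for pericentral and 0.32 for periportal genes.

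With slide ignored, the real split gave the highest count in both replicated comparisons. Such splits treat arrays of different slides as interchangeable, although slide set the arrays apart, so they do not exclude chance. With slide kept the splits are too few to tell. Of the 35 splits of the 8 MycF/F,ERT2-Cre arrays, 1 (the real one) gave as many as 4114 genes, and the highest other gave 299. Of the 35 splits of the 7 arrays on Wy-14643, 1 (the real one) gave as many as 17 genes, and the highest other gave 1. Splits that keep each slide's numbers of both groups were 18 and 12. The highest others gave 299 and 0, and the smallest possible shares were 0.0556 and 0.0833. The count of 17 fell to 0 without any 1 of 6 arrays.

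DNA replication genes were lower in MycF/F,ERT2-Cre than in MycF/F livers on Wy-14643, by more on slide 1 (-1.53) than on slides 2 and 3 (-0.54 and -0.43). The list call in this comparison did not hold with an estimated correlation. Without the 4 arrays of slide 1 the median was still -0.51, which argues against that slide as the whole source. As to a lower share of Kupffer cells and macrophages, their list was higher in the same comparison (median 0.31), a call lost with an estimated correlation. Marker levels in bulk RNA cannot tell the share of these cells from expression per cell, so that source of the drop is not excluded. A genotype effect that depends on the drug may explain part of it (interaction median -0.63), but it cannot be told apart from a difference already there on control diet, since the interaction rests on 1 MycF/F control array and had adjusted p = 0.416 with an estimated correlation. Without slide 1 the interaction median was -0.04. The -0.63 thus leans on slide 1, which held no MycF/F control array. Slide 2 alone held all 4 groups, with 1 array each. There the list mean was 0.26 in MycF/F and -0.19 in MycF/F,ERT2-Cre livers on control diet, and 0.24 and -0.28 on Wy-14643. On that slide the genotypes lay apart on both diets, though single arrays have no measured spread.

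The 3 Myc probes gave different sizes of the genotype effect on Wy-14643, -1.85 and -1.83 for 2 dimmer probes against -0.57 for the brightest. With the outlier spots of the brightest probe kept it gave -0.51, so the left-out spots do not explain the gap. Saturation of the brightest probe was found in 0 spots. That the brightest probe reads sequence outside the deleted part, or another transcript, is a candidate explanation that stays open, since its own drop on the drug in MycF/F,ERT2-Cre livers (-0.40) decides nothing and the probe could not be placed on the gene.

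Kupffer cell and macrophage markers were lower on Wy-14643 in MycF/F,ERT2-Cre livers (median -0.61), a list call that did not hold with an estimated correlation. Dilution of all non-parenchymal RNA alike stays open, although the list's median differed by -0.38 from that of 55 other non-parenchymal members. By list medians the difference was -0.49, -0.40 and -0.01 on slides 1, 2 and 3, and with arrays as the units the exact p was 0.0286 with slide ignored and 0.0556, the lowest possible, over the 18 splits within slides. Fewer Kupffer cells or macrophages may explain the drop, with 14 of 15 members below 0, but lower expression per cell would do the same, and the 2 cannot be told apart in bulk RNA. No symbol of the list is in another list, and its brightest members were Cd5l (-1.08), Clec4f (-0.76) and Lyz2 (-0.44, adjusted p = 0.209).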

How the results depend on the processing

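Keeping the outlier spots and leaving out the 4 arrays of slide 1 were chosen after the data were seen, and the other settings were set before. The cause was not tested for any change given here. The count for Wy-14643 in MycF/F,ERT2-Cre livers (4114) moved by over 1.5 times only on Cy5 alone (899), and ran from 3110 to 4114 when single arrays were left out. The count in MycF/F livers (1635) moved to 1054 on the deposited log ratios, 132 on Cy5 alone and 2830 without slide 1, with 1097 to 1894 when single arrays were left out. The count between genotypes on Wy-14643 (17) was 63 without background correction, 0 on the deposited log ratios, 0 on Cy5 alone, 27 with the mean over probes, 46 with only the groups compared, 36 with trend and robust eBayes, 359 with array weights, 41 with outlier spots kept and 107 without slide 1. With the slide block it was 33 and with the replicate block 0, and when single arrays were left out it ran from 0 (any of the 3 MycF/F Wy-14643 arrays, or MycF/F,ERT2-Cre Wy-14643 replicate 2, 3 or 4) to 27. Between genotypes on control diet 2 genes passed without slide 1 and 0 otherwise, and 0 passed in any setting for the interaction. The fit on only the compared groups exists for the 2 replicated comparisons alone, and the lone MycF/F control array could be left out only in those.

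Of the list calls over the 5 comparisons (76), 22 passed with an estimated correlation, 62 to 81 passed in the other settings, and 70 to 79 when single arrays were left out. List values are medians, and a list counts as turned when its test changes direction and it is called in either fit. Among single results Ncr1 turned to 0.072 on Cy5 alone with Wy-14643 in MycF/F,ERT2-Cre livers. The bile acid list turned to 0.38 on Cy5 alone and 0.13 with outlier spots kept between genotypes on control diet, and to -0.49 on Cy5 alone in the interaction. ER stress genes turned to -0.48 with the replicate block between genotypes on control diet, and G2/M genes to 0.0473 without slide 1 in the interaction. Leaving out MycF/F,ERT2-Cre control replicate 4 turned the urea cycle list on control diet (range -0.0435 to 0.235) and, in the interaction, the peroxisomal (-0.122 to 0.0802) and pericentral lists (-0.137 to 0.00356).

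Of the results for named genes with the drug in MycF/F,ERT2-Cre livers 2522 kept their call, 87 lost it, 3 gained it and 1 reversed, over all settings. A result called neither in the main fit nor in the alternative counts as kept even where its sign changed, and Aquantile is among the settings. Between genotypes on Wy-14643 the figures were 1276, 170, 6 and 0, and in MycF/F livers 1862, 125, 22 and 0. Results for lists, counted the same way, kept their call in 907 and 884 cases in the 2 replicated comparisons, and lost it in 27 and 47. Aquantile leaves the log ratios within arrays untouched and so tests nothing here. Scan time was not run apart from slide, since each slide had 1 scan. Of pairs with the same replicate number 7 of 10 had a residual correlation above 0.1, against 9 of 30 with different numbers. On the same slide 12 of 13 pairs did, and number and slide partly overlap. Whether the numbers pair the samples therefore cannot be told. The replicate block (0 genes between genotypes on Wy-14643) is not read as a pairing. On Cy5 alone the median of all genes was -0.11 for MycF/F livers and 0.14 for the interaction, against -0.00 and 0.03 on the ratios. Signal over background (2.69 to 4.76) limits dim genes, and whether it does so equally in the groups was not tested.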

Other observations

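All tests in this part were chosen after the data were seen. The cytosolic ribosomal protein and tubulin groups hold genes already called between genotypes on Wy-14643 (Rplp1, Rpl12, Rps12 and Tubb6). The p-values of both groups in that comparison are therefore no separate support. Proteasome subunit genes (38), 1 of 12 groups outside the 35 lists, over which the camera p-values here are adjusted, rose on Wy-14643 in MycF/F,ERT2-Cre livers with a median of 0.84, 34 higher and 3 lower by limma (camera adjusted p = 2.87e-26, and 0.0021 with an estimated correlation). The median was 0.72, 0.84 and 0.92 on slides 1, 2 and 3, and 0.86 with slide as a block. In MycF/F livers it was 0.66 (19 higher and 2 lower, adjusted p = 0.00289 with an estimated correlation). The immunoproteasome subunits Psmb8 (-1.52, SE 0.14), Psmb9 (-1.30, SE 0.29) and Psmb10 (-1.31, SE 0.09) went the other way in MycF/F,ERT2-Cre livers, with adjusted p = 1.25e-05, 0.00863 and 1.76e-06, as they did on all scalings tried. These subunits replace the catalytic subunits of the standard proteasome in cells that answer interferon. Chaperonin CCT subunit genes (8), which fold actin and tubulin, rose too (median 0.39, 6 higher, adjusted p = 0.0156 with an estimated correlation, and 0.0777 without MycF/F,ERT2-Cre control replicate 4), and had a median of 0.54 in MycF/F livers (4 higher, adjusted p = 0.00745 with an estimated correlation). Between genotypes on Wy-14643, where 0 genes of either group were called, CCT genes had a median of -0.25 and proteasome genes 0.14 (adjusted p = 0.00736 and 0.0107 with an estimated correlation). The proteasome interaction median, which rests on 1 MycF/F control array, was 0.17. It passed with an estimated correlation, but not without slide 1 or without MycF/F,ERT2-Cre control replicate 4.

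Cytosolic ribosomal protein genes (76) were lower in MycF/F,ERT2-Cre than in MycF/F livers on Wy-14643, with a median of -0.38, 74 members below 0 and 3 called lower (adjusted p = 0.014 with an estimated correlation, 0.023 with slide as a block and 0.067 without slide 1). The slide medians were -0.19, -0.30 and -0.49, and without single arrays the median ran from -0.42 to -0.33. On the drug the group was at 0.40 in MycF/F livers, with 9 genes higher and adjusted p = 0.107 with an estimated correlation. In MycF/F,ERT2-Cre livers it was at 0.05 (5 higher, 2 lower, adjusted p = 0.905 with an estimated correlation). The interaction median was -0.32 (adjusted p = 0.0387 with an estimated correlation, 0.0636 with slide as a block, 0.185 without slide 1 and 0.102 without MycF/F Wy-14643 replicate 3). Of 76 mitochondrial ribosomal protein genes 43 were higher in MycF/F,ERT2-Cre livers on the drug. The median of the group was 0.32 (adjusted p = 0.052 with an estimated correlation). In MycF/F livers the median was 0.39, which passed with an estimated correlation but not without MycF/F Wy-14643 replicate 1. Tubulin genes (12) and translation factor genes (65) had medians of -0.09 and -0.11 between genotypes on Wy-14643, with 1 and 0 called lower and adjusted p = 0.0197 each with an estimated correlation. Both had 0.0538 without MycF/F Wy-14643 replicate 3. For tubulin genes the slide medians were 0.01, -0.11 and -0.13. Their interaction median was -0.11, and their median in MycF/F livers on the drug was 0.24. Both passed with an estimated correlation, but neither did without MycF/F,ERT2-Cre Wy-14643 replicate 3. The interaction did not pass without slide 1 either.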
